A study of Mus musculus with 23 samples.

How the data were processed

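Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 23 libraries of innate lymphoid cells (ILCs) and natural killer (NK) cells from the small intestine (SI) or large intestine (LI) of C57BL/6 mice. Per the labels, all animals were wild type and at steady state. Groups, replicate numbers and 5 preparation batches were taken from the sample titles and source names: batch AD, batch SILP and 3 dated batches. Per the submitters' processing notes the authors used Bowtie2 2.2.3, SAMtools, Picard, HTSeq and DESeq2 on the mm10 build, and the notes do not state the role or settings of each. The peak caller, the gene annotation and the motif scanner were not given in the sources used here.

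The deposited accessibility table held 65281 peaks as variance-stabilised log2 values, which the authors had scaled for library depth. The authors' deposited table of 18 comparisons gave a log2 fold change with its standard error, a p-value and an adjusted p-value for each peak. Its other deposited columns were the peak length in bp, motif hits for 873 transcription factor names, the gene of the nearest transcription start site (TSS) with its distance in bp, and the genes within 10000 bp. Of the 65281 peaks, 65272 were in that annotation, 9 were not, and 52483 had a gene within 10000 bp, which gave 20345 genes. Peaks were 100 to 3750 bp long, with a median of 375 bp.

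The transform was inverted to see what depth lay behind the values. All 23 columns shared a lowest value of 4.34, and after inversion 100% of the 1448528 values above it were whole read counts within a tolerance of 0.001, with a largest distance of 3.3e-05. Size factors recomputed from those reads differed from the deposited ones by at most 1.52%. Reads in peaks ranged from 1559604 to 16257313 per library, a 10.4-fold range, with a median of 5802814 and a sum of 145676714. Reads given for a peak are scaled for depth. The interval of a share of peaks covers counting error only.

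Peaks were compared with limma 3.58.1 in R 4.3.3 on the deposited values: lmFit with 1 mean for each of the 11 groups over all 23 libraries, contrasts.fit, and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment over all peaks of a contrast. A peak was called at an adjusted p below 0.05. Groups of 1 library added nothing to the spread and were assumed to vary like the other groups. LI against SI was fitted on 10 libraries that form 5 pairs with the same date and cell subset, with subset as a term. For gene loci the same fits were made on the mean value over all peaks that the deposited annotation assigned to a gene, adjusted over all genes, and for a fixed list also adjusted over the list alone. Lists were tested against all other genes with camera at a preset correlation of 0.01, and again with the correlation estimated, with adjustment over the lists of a contrast. Shares of motif families among called peaks were compared by Fisher's exact test, two-sided, over peaks and not over samples. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

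Comparisons, alternatives, lists and the rule for named genes were set before the data were examined. For each of the 8 comparisons of cell types or tissue that rule named 4 peaks in each direction: those with the largest difference among called peaks with a gene, in which every library of one side lay above every library of the other, with 1 peak per gene. It also named, called or not, the 6 genes with the largest absolute moderated statistic in each of the 2 lists assigned to the comparison, and the 4 transcriptional regulators with the largest. Some items that this rule named, and 1 motif family, are not reported here, while the counts of calls and of list genes include them. For the 3 tissue comparisons within or between ILC1 and ILC3 it named the 3 loci with the largest statistic in each direction. The 20 lists were the ILC3, CCR6+ LTi-like (lymphoid tissue inducer), NCR+ CCR6- ILC3, group 1 (ILC1 and NK), NK, ILC1 and ILC2 programs; MHC class II; transcriptional regulators; migration and tissue homing; aryl hydrocarbon receptor response; circadian clock; immediate early and dissociation stress; neuropeptide and transmitter receptors; T cell, B cell, myeloid, mast cell, and epithelial markers; and housekeeping promoters.

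Replicate numbers were checked for pairing by correlating, across peaks, the deviations of same-numbered libraries from their group means. For CCR6+ and CCR6- ILC3 these were 0.313, 0.267 and 0.557, above the 0.1 that was set as the limit, so these libraries were treated as paired in an alternative. Differently numbered libraries of batch AD gave 0.318 and 0.270, so the pairing followed the batch. LI and SI pairs were taken from the titles, which give a shared date. The labels do not say that replicates are separate animals. Reads in Y-linked peaks differed between replicates 1 and 2 of SI ILC1 (451 and 0) and of NK (787 and 0). They differed too between SI exILC3 replicates 4 and 3 (932 and 0). Replicates 1 and 3 had 2034 and 0 in SI CCR6+ ILC3 and 787 and 0 in SI CCR6- ILC3. Such replicates thus came from different animals. Replicates that both have Y-linked reads, as in ILC2, may still share animals. P-values measure only the spread between libraries, and how much of it is technical is not known.

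Alternatives mostly changed 1 choice at a time, but some within-batch fits and blocks also changed the libraries, the cell group or the terms: leaving out the peaks with the lowest mean values (under 5.39), quantile normalization, a robust spread without trend, a difference of at least 1 as well as the adjusted p, batch as a term, only the compared libraries, within-batch fits, replicate blocks, the largest peak of a locus in place of its mean, and leaving out each library. After the data were seen, 4 more were added: voom on the recovered reads, the values recomputed after thinning every library at random to 1559604 reads, autosomal peaks only, and leaving out each library in the 3 tissue comparisons of ILC1 and ILC3, except the 2 LI ILC3 libraries, each the only one of its group.

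The limma fits were tested on simulated data with 65281 peaks, of which 100 changed 2-fold and 100 changed 4-fold. The calls found 25% and 70.0% of these for CCR6+ against CCR6- ILC3, 16% and 72% for ILC2 against ILC3, 30.0% and 88% for ILC1 against ILC3, and 19% and 70.0% for ILC2 against ILC1. They found 15% and 72% for NK against ILC1, 18% and 67% for exILC3 against ILC1, 11% and 51% for exILC3 against CCR6- ILC3, and 27% and 71% for LI against SI. For LI against SI within ILC1 they found 24% and 66%, and within ILC3 43% and 77%. False calls were 86.0% of the calls for LI against SI ILC3 (737 of 857), 20.4% for LI against SI ILC1, 20.2% for NK against ILC1, 17.4% for CCR6+ against CCR6- ILC3, 12.7% for exILC3 against CCR6- ILC3 and 3.26% to 9.28% in the others. With no change simulated, 0 to 3 peaks were called, except 566 for LI against SI ILC3. Every comparison called more peaks in the data than were changed here, and simulated libraries varied independently without batches. Recovery and false calls may thus differ in the data.

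A search for consensus motifs needed the mm10 sequence and was not run, edgeR and DESeq2 were not run, and raw reads were not analysed here.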

Results

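ATAC-seq measured how open the chromatin was at 65281 peaks in sorted ILCs and NK cells of the mouse intestine at steady state. ILC1, ILC2 and ILC3 are tissue-resident lymphocytes without antigen receptors that make type 1, type 2 and type 3 cytokines, and ILC3 were split by the chemokine receptor CCR6. The exILC3 group, as its name states, holds cells that were once ILC3, and how they were marked is not given in the sources used here. Small intestine (SI) groups were CCR6+ ILC3 (n = 3), CCR6- ILC3 (n = 3), ILC2 (n = 2), ILC1 (n = 4), NK (n = 2), exILC3 (n = 2) and a sort named as ILC1 and NK together (n = 2). Large intestine (LI) groups were ILC1 (n = 2) and 1 library each of CCR6+ ILC3, CCR6- ILC3 and exILC3. Values are variance-stabilised log2 accessibility as the authors deposited it, differences are between group means on that scale, and a locus is the mean over the peaks assigned to a gene. In simulated libraries a 4-fold change of reads in CCR6+ against CCR6- ILC3 gave a median difference of 1.11, so the scale compresses folds at low reads.

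Depth in peaks differed between groups. SI CCR6+ ILC3 had 14033445, 6814274 and 5802814 reads, SI CCR6- ILC3 6769207, 14599971 and 7209765, and ILC2 7089681 and 10026971. SI ILC1 replicates 1 to 4 had 2924479, 3821695, 5412135 and 7223582, NK 5467630 and 1810055, and SI exILC3 replicates 3 and 4 2510137 and 7415963. The sort of ILC1 and NK had 16257313 and 7262292 reads. Each LI library was shallower than the SI library of the same subset and date. LI libraries had 2118302 and 4233090 reads for ILC1, 3653555 for exILC3, 1660754 for CCR6- ILC3 and 1559604 for CCR6+ ILC3. Of the peaks, 47655 had at least 1 read in every library and 25.4% lay within 1000 bp of a TSS. Replicates correlated across peaks at 0.933 to 0.987, and their differences exceeded sampling noise in every pair, with a chi-square per degree of freedom of 2.02 to 6.49.

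Cell type set the main axes of the data. The first principal component held 48.5% of the variance and ran from CCR6+ ILC3 over CCR6- ILC3 and exILC3 to ILC1 and NK. The next component, with 18.6%, set ILC2 apart from all other groups, and a further one held 8.20%.

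**Figure D1:**
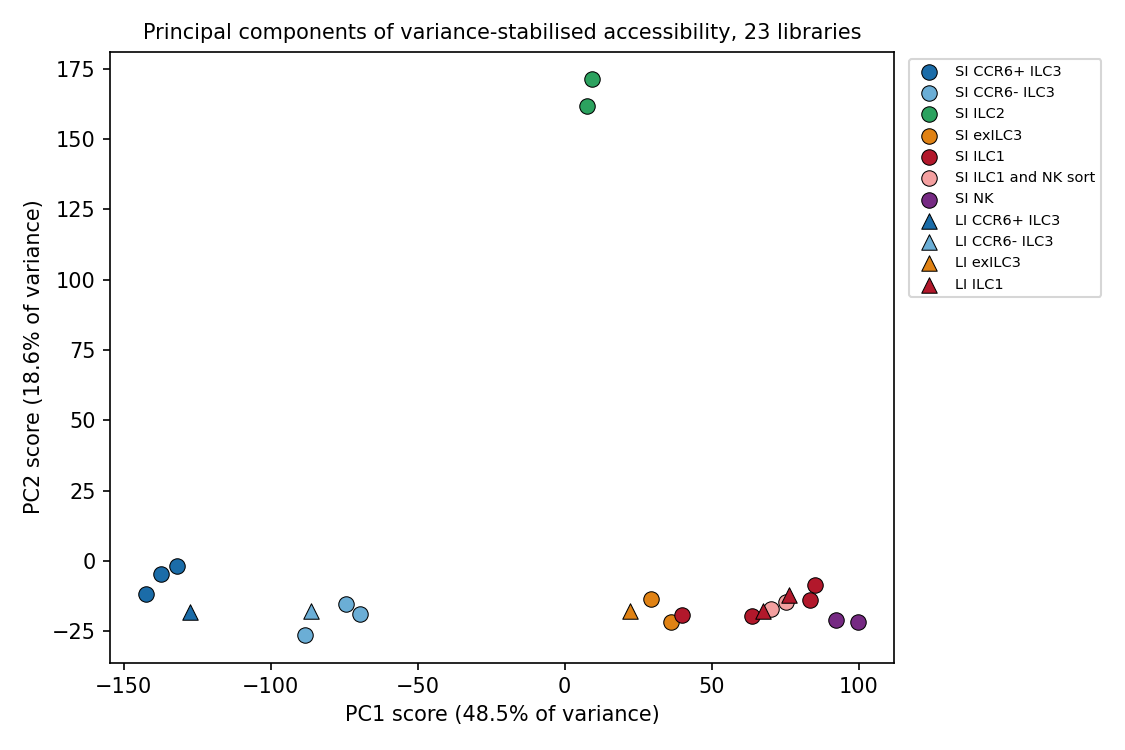
Scores of the 23 libraries on the first (x, 48.5% of variance) and the next principal component (y, 18.6%) of the log2 accessibility values; each point is 1 library, coloured by the 11 groups, with circles for SI and triangles for LI. SI CCR6+ ILC3 lie between -142.41 and -131.79 on x, SI exILC3 at 29.44 and 36.24 and NK at 92.24 and 99.74, while ILC2 lie at 171.19 and 161.56 on y.

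CCR6+ against CCR6- ILC3 asked how the LTi-like subset, which helps to build lymphoid tissue, differs from the subset that can express the receptor NKp46. Accessibility rose in CCR6+ cells at Ccr6 itself and at Il17a and Il17f, which encode cytokines that defend mucosa. It rose also at Cxcr5, a receptor for homing to B cell follicles, at the surface receptor gene Nrp1 and at the adhesion gene Cntn1. Accessibility fell at Ncr1, which encodes NKp46, at Tbx21, which encodes the type 1 regulator T-bet, at Ifng, at the chemokine genes Xcl1 and Ccl3 and at the granzyme gene Gzmb. Among regulators, Tox2 rose, while Bcl11b, a T lineage factor that ILC2 also need, and Lef1 fell.

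Ccr6 had a mean of 6.09 ± 0.05 (SD, n = 3) in CCR6+ and 5.11 ± 0.06 (SD, n = 3) in CCR6- ILC3, a difference of 0.98 (SE 0.12, adjusted p = 1.42e-05). Ncr1 fell by 1.12 (SE 0.10, adjusted p = 9.74e-07), from 6.27 ± 0.20 to 5.15 ± 0.05. Il17a rose by 0.64, Il17f by 0.49, Tox2 by 0.49, Cxcr5 by 0.37, Cntn1 by 0.34 and Nrp1 by 0.28. Other lower loci were Xcl1 (-0.88), Ccl3 (-0.73), Ifng (-0.70), Bcl11b (-0.67), Tbx21 (-0.50), Gzmb (-0.45) and Lef1 (-0.29). Of 18 LTi-like loci, 6 rose, 0 fell and 12 were not called, the same when adjusted over the list alone. Of 19 NCR+ loci, 0 rose, 8 fell and 11 were not called, with 9 lower adjusted over the list alone, and the list as a whole was lower (adjusted p = 0.000262, and adjusted p = 0.778 with an estimated correlation). Of 24 group 1 loci 10 fell and 0 rose (12 adjusted over the list alone), and of 18 ILC1 loci 4 fell, with Itga1 at -0.55. The gene with the largest statistic was Cd74 at 0.84 in MHC class II, Ccr9 at -0.74 in homing, Nr4a2 at 0.47 in the immediate early list and Actb at 0.34 in housekeeping promoters.

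Of the named peaks with the largest differences, those at Unc5c and at App lay within 1000 bp of a TSS. A peak at -425 bp from the TSS of Unc5c, a netrin receptor gene (chromosome 3, 141464463 to 141465812, mm10, 1-based), rose by 3.11 (SE 0.22, adjusted p = 6.44e-10), with 432.5 ± 86.6 against 19.6 ± 7.73 depth-scaled reads (SD, n = 3 each). Other higher peaks were at Hdac9, a histone deacetylase gene (2.81), at App, the amyloid precursor gene, and Gm10791 (2.76), and at Pyroxd1 (2.71). The peak at App and Gm10791 lay 78 bp from the TSS of Gm10791. A peak at 1700065J11Rik (chromosome 6, 35337488 to 35338012) fell by 2.88 (SE 0.23, adjusted p = 3.61e-09), and further lower peaks were at P2rx3, an ATP-gated channel gene (-2.75), Samd12 (-2.42) and the gene pair Glcci1 and Umad1 (-2.26). Higher peaks lay within 1000 bp of a TSS in 19.3% of cases, lower peaks in 11.05% and all peaks in 25.4%.

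In all, 6939 peaks rose and 5558 fell at an adjusted p below 0.05 (limma), 55.5% higher, and 3991 loci passed, 2282 higher. The share was 48.01% with the lowest peaks left out. Reads thinned to equal depth gave 7656 calls, voom on the reads gave 19030, and leaving out CCR6- ILC3 replicate 1 gave 7894. With the replicate number as a block 12686 peaks were called. Nrp1 lost its call without any 1 of the 6 libraries, Cxcr5 and Cntn1 lost theirs without any of 5, and all 3 lost it with voom and with the lowest peaks left out, where Cntn1 was at 0.16 (adjusted p = 0.506). Il17a and Gzmb lost their call in 1 alternative each and Lef1 in 2.

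ILC2 against ILC3 set the type 2 subset, which drives antiparasite and allergic responses, against both ILC3 subsets. Accessibility rose in ILC2 at Il4, which encodes a type 2 cytokine, at Il9r, which encodes a survival receptor, at Ptgir, the prostacyclin receptor gene, at Calca, which encodes a neuropeptide, at Bmp7, a growth factor gene, and at the heparan sulfate enzyme gene Hs3st1. It fell at the cytokine and receptor genes Il17f, Il23r, Il1r1 and Ccr6. Batf3, which encodes a dendritic cell factor, fell as well. Among regulators Bcl11b and Irf4 rose and Tox2 fell.

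Ptgir had a mean of 6.93 ± 0.06 (SD, n = 2) in ILC2 and 5.06 ± 0.11 (SD, n = 6) in ILC3, a difference of 1.86 (SE 0.10, adjusted p = 2.73e-10). Il17f fell by 1.74 (SE 0.10, adjusted p = 3.37e-10), from 6.65 ± 0.29 to 4.91 ± 0.03. Other higher loci were Il4 (1.95), Bmp7 (1.92), Hs3st1 (1.91), Il9r (1.71), Calca (1.62), Bcl11b (0.95) and Irf4 (0.85). Other lower loci were Il23r (-1.75), Il1r1 (-1.40), Ccr6 (-0.93), Batf3 (-0.87) and Tox2 (-0.83). Of 28 ILC2 loci, 20 rose, 1 fell and 7 were not called, the same adjusted over the list alone (adjusted p = 2.9e-07 for the list, and adjusted p = 0.0149 with an estimated correlation). Of 20 ILC3 loci, 4 rose, 9 fell and 7 were not called, the same adjusted over the list alone. LTi-like loci fell in 10 of 18 cases and rose in 2 (adjusted p = 0.024, and adjusted p = 0.564 with an estimated correlation). Of 9 MHC class II loci 7 rose, with H2-DMa at 0.45. The median of the NK list was 0.05 and its mean -0.08, and of the homing list 0.11 and -0.08, with both set tests pointing down.

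The largest single rise was at a peak near Spcs3, a signal peptidase gene (chromosome 8, 54520888 to 54521962), of 4.80 (SE 0.19, adjusted p = 2.16e-15), with 907.1 ± 46.5 against 4.34 ± 2.38 depth-scaled reads. Lsamp, a neuronal adhesion gene (4.45), 1700112E06Rik (4.28) and Ltbp1, a TGF-β binding gene (4.24), followed. A peak 31715 bp from the TSS of Diaph3, a formin gene (chromosome 14, 86757663 to 86758737), fell by 5.01 (SE 0.25, adjusted p = 5.08e-14). It had 1.22 ± 0.32 depth-scaled reads in ILC2 (SD, n = 2) and 942.9 ± 416.4 in ILC3 (SD, n = 6). Peaks at Dppa2 (-4.86), Wdr27 (-4.81) and Musk (-4.72) fell too. Of the higher peaks 24.8% lay within 1000 bp of a TSS, and of the lower peaks 11.6%.

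Between ILC2 and ILC3, 15043 peaks rose and 17537 fell, 46.2% higher, and 10090 loci passed, 5547 higher. The share was 51.3% after quantile normalization and 50.3% with voom. Batch AD alone held ILC2 and ILC3 together, and there 41891 peaks were called.

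ILC1 against ILC3 set type 1 cells, which make interferon gamma, against type 3 cells. Accessibility rose in ILC1 at Ifng, at Gzma and Fasl, whose products kill target cells, at the chemokine genes Xcl1 and Ccl4 and at Il12rb2, the receptor gene for interleukin 12. It fell at Il17a, Il17f, Il22, Il1r1, Ccr6 and Batf3. Among regulators Tbx21, Stat3 and Bhlhe40 rose and Tox2 fell.

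Ifng had a mean of 7.01 ± 0.25 (SD, n = 4) in ILC1 and 5.12 ± 0.40 (SD, n = 6) in ILC3, a difference of 1.89 (SE 0.09, adjusted p = 6.08e-11). Gzma rose by 1.76 (SE 0.07, adjusted p = 1.27e-11) and Tbx21 by 1.18 (SE 0.10, adjusted p = 2.07e-08). Fasl (1.51), Ccl4 (1.47), Xcl1 (1.39), Il12rb2 (1.14), Stat3 (0.67) and Bhlhe40 (0.46) were also higher. Il17a fell by 1.90 (SE 0.12, adjusted p = 7.44e-10), and Il22 (-1.80), Il17f (-1.56), Il1r1 (-1.38), Tox2 (-1.014), Ccr6 (-0.83) and Batf3 (-0.79) were also lower. Of 24 group 1 loci, 15 rose, 0 fell and 9 were not called, the same adjusted over the list alone (adjusted p = 1.89e-06 for the list, and adjusted p = 0.302 with an estimated correlation). Of 20 ILC3 loci, 0 rose, 14 fell and 6 were not called, the same adjusted over the list alone (adjusted p = 6.26e-05, and adjusted p = 0.302 with an estimated correlation). NK loci rose in 13 of 19 cases and fell in 4, and ILC1 loci rose in 8 of 18 and fell in 3, with Tnfsf10 at 0.65. In the homing list 8 rose and 4 fell, and in the circadian list 2 rose and 4 fell, with Nr1d2 at -0.77. Of 6 aryl hydrocarbon receptor loci 2 rose and 1 fell, with Ahrr at 0.89, and of 8 neuropeptide loci 2 rose and 3 fell, with Vipr2 at -0.60.

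The largest rise was at a peak of Atp10a, a lipid flippase gene (chromosome 7, 58824563 to 58825587), of 3.93 (SE 0.18, adjusted p = 5.66e-15), with 817.9 ± 110.6 against 25.1 ± 24.9 depth-scaled reads. Peaks at Rttn and Mir6359 (3.65), at Man2b2 (3.63) and at Bst1, a stromal antigen gene (3.62), were also higher. A peak at Slc9c1, an ion exchanger gene (chromosome 16, 45561013 to 45562462), fell by 3.92 (SE 0.19, adjusted p = 1.8e-14), and so did peaks at Nsl1 and Tatdn3 (-3.90), Flrt2 (-3.81) and Dppa2 (-3.54).

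For ILC1 against ILC3, 15547 peaks rose and 18988 fell, 45.02% higher, and 10047 loci passed, 4716 higher. The share was 52.9% after quantile normalization and 51.1% with the lowest peaks left out. No batch held both SI ILC1 and SI ILC3. With batch as a term 18602 peaks were called, 7538 higher and 11064 lower. The batches of ILC1 and of ILC3 were linked only by SI exILC3 replicates 3 and 4, so that fit rests on the difference between these libraries. Within batch AD, with the sort of ILC1 and NK in place of ILC1, 40279 peaks were called.

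ILC2 against ILC1 contrasted type 2 with type 1 cells. Accessibility rose in ILC2 at Il5, which encodes the eosinophil cytokine, at Il9r, Ptgir and Calca, at Pparg, a lipid sensor gene that ILC2 need, and at Hs3st1. It fell at Ncr1, Ifng, Xcl1, Ccl4, Gzmb and Il12rb2. Among regulators Irf4 and Klf2 rose, while Bhlhe40 and Zbtb16, which encodes the ILC precursor factor PLZF, fell.

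Hs3st1 had a mean of 6.76 ± 0.07 (SD, n = 2) in ILC2 and 4.68 ± 0.10 (SD, n = 4) in ILC1, a difference of 2.08 (SE 0.11, adjusted p = 3.93e-10). Ifng fell by 2.00 (SE 0.12, adjusted p = 2.23e-09) and Ncr1 fell by 1.83 (SE 0.10, adjusted p = 7.43e-10). Higher loci were Pparg (1.76), Il9r (1.71), Il5 (1.65), Ptgir (1.64), Calca (1.42), Irf4 (1.10) and Klf2 (1.05). Lower loci were Xcl1 (-1.73), Ccl4 (-1.59), Gzmb (-1.501), Il12rb2 (-1.12), Zbtb16 (-0.82) and Bhlhe40 (-0.80). Of 28 ILC2 loci, 20 rose, 2 fell and 6 were not called, the same adjusted over the list alone (adjusted p = 1.2e-07, and adjusted p = 0.0157 with an estimated correlation). Of 24 group 1 loci, 1 rose, 17 fell and 6 were not called, the same adjusted over the list alone (adjusted p = 8.57e-12, and adjusted p = 0.138 with an estimated correlation). Of all lists called by the set test, only the ILC2 list, against ILC3 and against ILC1, held with an estimated correlation. NCR+ loci fell in 12 of 19 cases, NK loci in 12 of 19 and homing loci in 7 of 18, and these lists kept no call with an estimated correlation (adjusted p = 0.138, 0.138 and 0.275). Immediate early loci rose in 8 of 19 cases, with Fosb at 0.81, and circadian loci in 6 of 13, with Bhlhe41 at 1.23. For the regulators the median (0.01) and mean (0.03) were above 0 while the set test pointed down.

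Peaks at Spcs3 (4.73, SE 0.20, adjusted p = 5.57e-15), 1700112E06Rik (4.71), Lsamp (4.65) and Mthfd1l, a folate enzyme gene (4.52), rose most. The Atp10a peak fell by 4.49 (SE 0.24, adjusted p = 1.76e-13), and peaks at Gsap (-4.35), Sft2d2 (-4.34) and Bst1 (-4.19) fell too. In total 13845 peaks rose and 13357 fell, 50.9% higher, and 8103 loci passed, 4694 higher. With the lowest peaks left out the share was 40.9%, after quantile normalization 48.9% and with thinned reads 49.6%. No batch held ILC2 with ILC1. With batch as a term 13797 peaks were called, but the batches of ILC2 and ILC1 were linked only through ILC3 and SI exILC3 replicates 3 and 4. Within batch AD, with the sort of ILC1 and NK in place of ILC1, 35905 peaks were called.

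**Figure D2:**
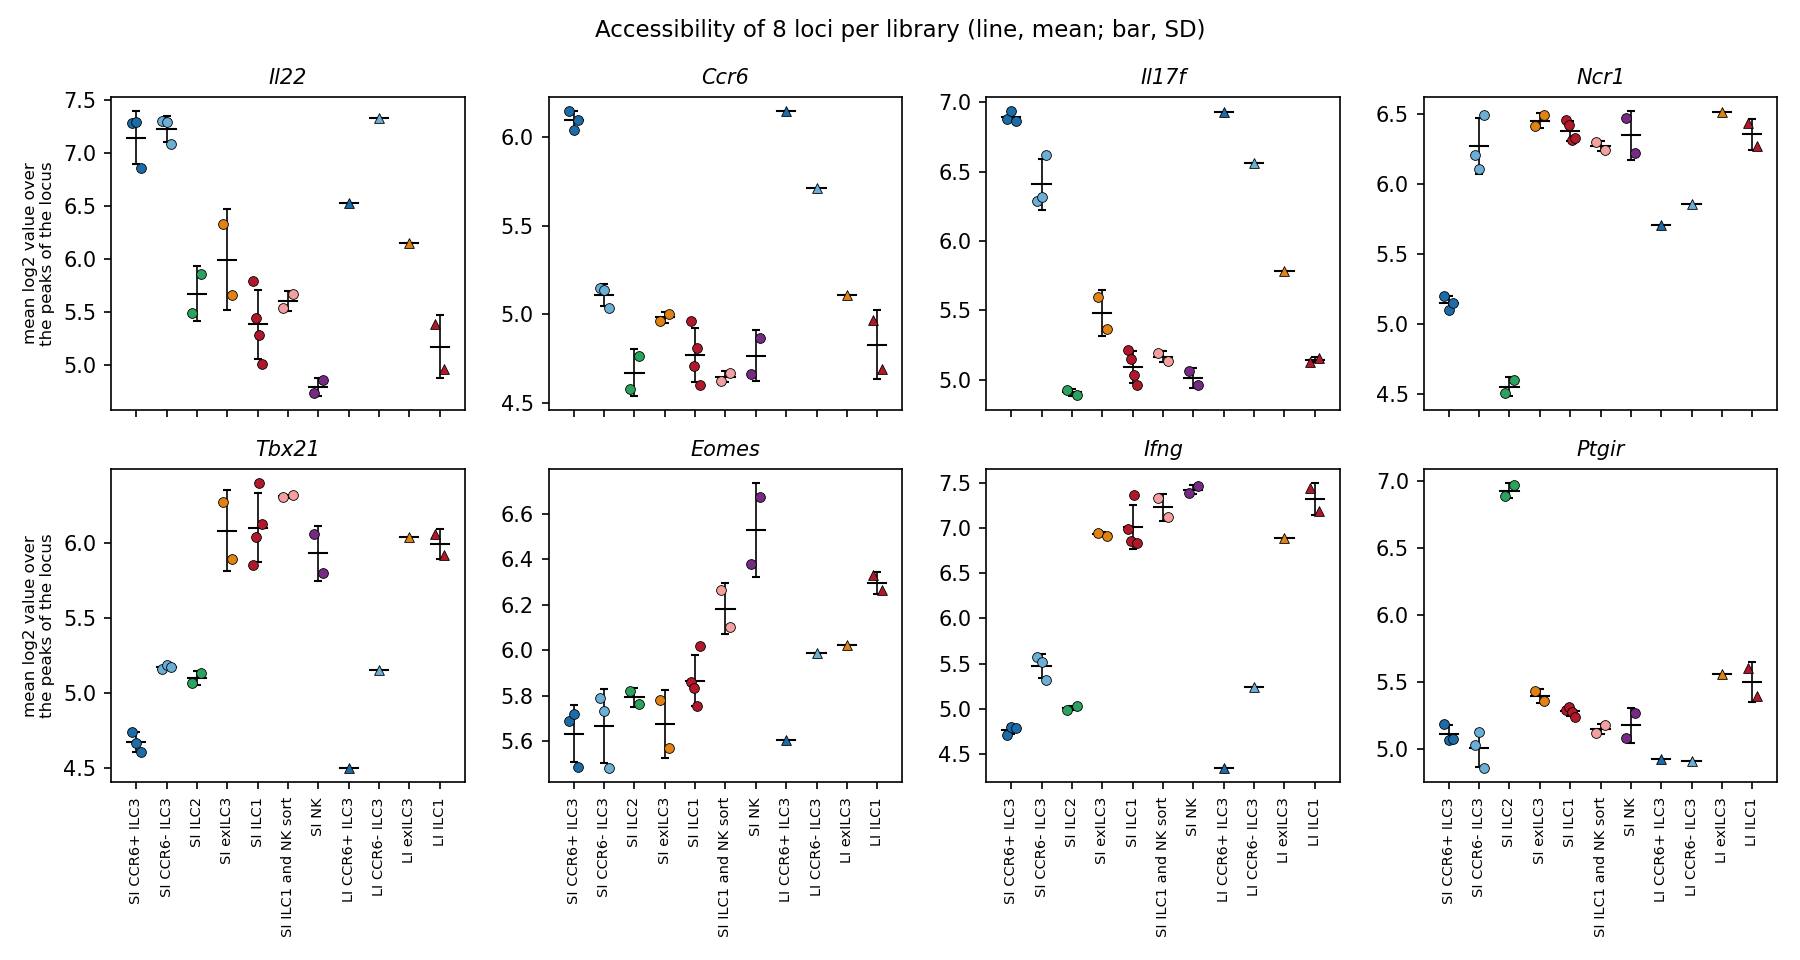
Mean log2 accessibility over the peaks of a locus (y) in the 11 groups (x) at Il22, Ccr6, Il17f, Ncr1, Tbx21, Eomes, Ifng and Ptgir; points are libraries, horizontal lines group means and bars the SD. Ptgir is at 6.93 in ILC2 and 5.06 in ILC3, Ifng at 7.01 in ILC1 and 5.12 in ILC3, and Ncr1 at 5.15 in SI CCR6+ and 6.27 in SI CCR6- ILC3.

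NK against ILC1 compared the 2 kinds of group 1 cells. Accessibility rose in NK cells at Eomes, which encodes an NK regulator, at Gzma, at the receptor gene Klra8, and at Itga2, the CD49b gene used to mark NK cells. It fell at Il7r, which encodes the interleukin 7 receptor, at Cxcr6, a residency receptor gene, at Socs2, and at the regulator Ikzf2. Zeb2, Zbtb16, Rora, Tmem176a and Tmem176b were not called.

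Eomes had a mean of 6.53 ± 0.21 (SD, n = 2) in NK cells and 5.87 ± 0.11 (SD, n = 4) in ILC1, a difference of 0.66 (SE 0.11, adjusted p = 0.00207). Il7r fell by 0.56 (SE 0.10, adjusted p = 0.00331) and Cxcr6 fell by 0.56 (SE 0.12, adjusted p = 0.00891). Klra8 (0.72), Gzma (0.40) and Itga2 (0.29) were higher, and Ikzf2 (-0.34) and Socs2 (-0.29) lower. Values without a call were 0.27 for Zeb2, -0.33 for Zbtb16, -0.30 for Rora, -0.62 for Tmem176a and -0.46 for Tmem176b. Of 19 NK loci, 5 rose, 0 fell and 14 were not called, with 8 higher adjusted over the list alone (adjusted p = 7.59e-05, and adjusted p = 0.359 with an estimated correlation). Of 18 ILC1 loci, 0 rose, 3 fell and 15 were not called, with 5 lower adjusted over the list alone. The ILC3 list had 1 higher and 2 lower of 20 loci, 2 and 8 adjusted over the list alone (adjusted p = 0.00207, and adjusted p = 0.62 with an estimated correlation). No MHC class II, aryl hydrocarbon receptor, immediate early or housekeeping locus was called by limma, with 2, 2, 3 and 0 at an unadjusted p under 0.05. Peaks at Phactr3 (2.96, SE 0.18, adjusted p = 5.1e-10), Nrxn3, a synaptic adhesion gene (2.70), Ndufs4 (2.59) and N4bp1 (2.41) rose most. Peaks at Fat3 (-2.20), Plekhg1 (-2.03), Mast4 (-1.90) and Fam159b (-1.85) fell most.

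NK cells had 2991 higher and 2859 lower peaks than ILC1, 51.1% higher, and 1241 loci passed, 691 higher. Within batch SILP (2 libraries of each) 1023 peaks were called, with the replicate number as a block 2362, and with batch as a term 10863, 44.97% higher. With the lowest peaks left out the share was 47.6%, and without NK replicate 1 42.3%. Eomes kept no call in SILP alone (difference 0.68, adjusted p = 0.151), nor did Il7r (-0.66, adjusted p = 0.153) and Cxcr6 (-0.53, adjusted p = 0.241). Gzma, Klra8, Itga2, Socs2 and Ikzf2 kept no call in SILP alone (adjusted p = 0.162, 0.0918, 0.355, 0.348 and 0.454), with voom or with thinned reads. Tmem176a, Tmem176b and Zbtb16 gained a call with batch as a term (adjusted p = 0.0071, 0.0408 and 0.0422). Without NK replicate 2, the shallower library, 1355 peaks were called and Eomes had an adjusted p of 0.115. With voom 84.7% of 2537 calls were higher.

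The comparison of exILC3 with ILC1 asked where cells named as former ILC3 differ from ILC1. Whether a difference was kept from an earlier ILC3 state cannot be told from these values. The cytokine loci Il17f and Il22, the cytokine receptor locus Il23r, the receptor antagonist locus Il1rn and Batf3 were not called. Neither were the group 1 loci Ccl5, Ccl4, Gzma, Gzmb, Prf1 and Il2rb, nor the regulators Zeb2, Bhlhe40 and Ikzf1.

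Values without a call were 0.61 for Il22, 0.46 for Il1rn, 0.39 for Il17f, 0.29 for Il23r and -0.23 for Batf3, and for group 1 -0.41 for Ccl4, -0.34 for Ccl5, -0.30 for Gzma, -0.29 for Gzmb, -0.27 for Prf1 and 0.32 for Il2rb. Regulators without a call were Zeb2 (-0.28), Bhlhe40 (-0.20) and Ikzf1 (-0.19). Of 20 ILC3 loci, 1 rose, 0 fell and 19 were not called, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 4.08e-05, and adjusted p = 0.216 with an estimated correlation). Of 24 group 1 loci limma called 0, with 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.0391, and adjusted p = 0.664 with an estimated correlation). Of 19 NK loci limma called 0, with 10 at an unadjusted p under 0.05 and 6 lower adjusted over the list alone (adjusted p = 2.64e-06, and adjusted p = 0.175 with an estimated correlation). The circadian list also had 0 of 13 called, with 3 at an unadjusted p under 0.05 and Nr1d1 at 0.45 (adjusted p = 0.00513 for the list, and adjusted p = 0.216 with an estimated correlation).

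A peak of Mast4, a kinase gene (chromosome 13, 103246863 to 103248012, 87055 bp from the TSS), rose by 1.47 (SE 0.20, adjusted p = 0.00195), with 291.6 ± 26.9 against 85.6 ± 42.4 depth-scaled reads (SD, n = 2 and n = 4). Peaks at BC053393 (1.41) and Ston2 (1.35) were also higher. Lower peaks were at Gnptab (-1.24), AK140921 and Angpt1 (-1.21), St8sia1 (-1.19) and Gbp2b and Gbp7 (-1.16). With reads thinned to equal depth the peaks of Gbp2b and Gbp7 (adjusted p = 0.17) and of AK140921 and Angpt1 (adjusted p = 0.0776) lost their call.

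Between exILC3 and ILC1, 398 peaks rose and 411 fell, 49.2% higher, and 59 loci passed, 19 higher. In a fit of only these 6 libraries limma called 0 peaks, with 6159 at an unadjusted p under 0.05. In the design as reported voom called 1923, 67.1% of them higher. Thinned reads gave 83, batch as a term 2121 with 67.9% higher, and replicates 3 and 4 with the replicate number as a block 3644 with 69.3% higher. Only 1 batch held both groups, with 1 library of each. Without SI exILC3 replicate 4 the count was 253. Without SI exILC3 replicate 3 it was 505, and without SI ILC1 replicate 1, 2 or 3 it was 2256, 501 or 137.

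The comparison of exILC3 with CCR6- ILC3 asked where these groups differ, and CCR6- ILC3 need not be the cells that exILC3 came from. Accessibility rose in exILC3 at Ifng, Tbx21, Il12rb2, Xcl1, Ccl4 and Ccl5, the type 1 genes. It fell at Il17a, Il17f, Il22, Il1r1, Nrp1 and Batf3. Among regulators Stat3 and Bhlhe40 rose and Tox2 fell.

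Ifng had a mean of 6.93 ± 0.02 (SD, n = 2) in exILC3 and 5.47 ± 0.13 (SD, n = 3) in CCR6- ILC3, a difference of 1.46 (SE 0.13, adjusted p = 2.7e-06). Tbx21 rose from 5.17 ± 0.01 to 6.08 ± 0.27, by 0.91 (SE 0.14, adjusted p = 0.000186). Il12rb2 (1.013), Ccl4 (0.84), Xcl1 (0.81), Ccl5 (0.64), Stat3 (0.40) and Bhlhe40 (0.29) were also higher. Il17f fell by 0.93 (SE 0.11, adjusted p = 1.96e-05), and Il22 (-1.23), Il17a (-1.17), Il1r1 (-0.999), Batf3 (-0.81), Tox2 (-0.62) and Nrp1 (-0.40) were also lower. Of 20 ILC3 loci, 0 rose, 7 fell and 13 were not called, with 1 higher and 8 lower adjusted over the list alone (adjusted p = 0.00428, and adjusted p = 0.346 with an estimated correlation). Of 19 NCR+ loci, 7 rose, 0 fell and 12 were not called, with 8 higher adjusted over the list alone (adjusted p = 0.00023, and adjusted p = 0.346 with an estimated correlation). Group 1 loci rose in 9 of 24 cases and fell in 0, with Gzma at 1.27. Peaks at Atp10a (3.01, SE 0.25, adjusted p = 1.1e-08), Man2b2 (2.83), Rttn and Mir6359 (2.78) and Plek, a leukocyte signalling gene (2.74), rose most. Peaks at Flrt2 (-3.20, SE 0.28, adjusted p = 2.07e-08), Olfr175-ps1 (-2.75) and Slc9c1 (-2.66) fell most.

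For exILC3 against CCR6- ILC3, 5317 peaks rose and 8718 fell, and 3712 loci passed, 1316 higher. The share of higher calls was 37.9%, and 48.4% of 16130 calls after quantile normalization. Thinned reads gave 7919 calls, and leaving out SI exILC3 replicate 3 gave 7615. One batch held both groups, with 1 library of each, and Stat3, Nrp1 and Bhlhe40 lost their call in several alternatives.

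LI against SI compared the 2 tissues over 5 pairs with a shared date and subset. Accessibility fell in LI at Ccr9, the small intestine homing receptor gene, the only locus of the homing list that passed. S1pr1 and Cxcr4, which guide cells out of and into tissues, Gpr18 and Cyp26b1 were not called. The neuropeptide receptor genes Ramp1, Nmur1, Ret, Vipr1 and Calcrl were not called, nor were the regulators Prdm1, Eomes, Tox2 and Ikzf2.

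Ccr9 had a mean of 5.22 ± 0.22 (SD, n = 5) in LI and 5.77 ± 0.49 (SD, n = 5) in SI, a difference of -0.55 (SE 0.11, adjusted p = 0.0466). It was not called with the pairs as a replicate block (adjusted p = 0.0609), and over its alternatives the adjusted p of lost calls reached 0.173. Values without a call were 0.24 for S1pr1, 0.20 for Cxcr4, -0.24 for Cyp26b1 and -0.15 for Gpr18. Among neuropeptide receptors they were 0.29 for Ramp1, 0.14 for Ret, -0.25 for Nmur1, -0.13 for Vipr1 and -0.11 for Calcrl, and among regulators 0.34 for Eomes, 0.24 for Tox2, -0.30 for Prdm1 and -0.24 for Ikzf2. Of 18 homing loci, 0 rose, 1 fell and 17 were not called, the same adjusted over the list alone. Of 8 neuropeptide loci limma called 0, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Outside the named loci, Ccr8, a skin homing receptor gene in the ILC2 list, rose by 0.71 (adjusted p = 0.0241), Cd28 rose by 0.69 (adjusted p = 0.0119) and Cpa3 fell by 0.44 (adjusted p = 0.0426). These 3 loci were chosen after their values were seen, as the only list genes called besides Ccr9.

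A peak of Park2, the parkin gene (chromosome 17, 11550413 to 11551087), rose in LI by 2.11 (SE 0.20, adjusted p = 3.49e-05), with 194.8 ± 119.6 against 17.4 ± 13.8 depth-scaled reads (SD, n = 5 each). Peaks at Tpx2 and Mylk2 (1.78), Nek6 (1.71) and Ctnnd2 (1.61) were higher. SI NK libraries were not in this fit, and at Nek6 they had 482.3 and 530.3 depth-scaled reads, against 398.6 to 533.9 in LI. They lay within the LI range at Park2 and Ctnnd2 too, and at Tpx2 and Mylk2 in replicate 2 only. Values of this size were thus not particular to LI. Lower peaks lay at Wnk3 and A230072E10Rik (-0.99), at Prdm1, which encodes Blimp-1, 31161 bp from its TSS (-0.96), at 1810011H11Rik (-0.94) and at Lsamp (-0.92), and all of these lost their call with thinned reads (adjusted p = 0.0566 to 0.132).

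Across tissues 913 peaks rose and 586 fell, 60.9% higher, and 178 loci passed, 145 higher. With the pairs as a replicate block 1399 peaks were called. Thinned reads gave 158, voom called 1995 with 78.8% higher, and all 23 libraries in the fit gave 12262 with 41.1% higher. Leaving out a library gave 436 without LI exILC3, 440 without SI exILC3 replicate 4, 697 and 736 without SI ILC1 replicates 3 and 4, 802 without LI CCR6- ILC3, 822 without SI CCR6- ILC3 replicate 3 and 936 without LI ILC1 replicate 3.

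Within ILC1, LI cells had higher accessibility at Tmem171, a membrane protein gene, at 1700019C18Rik and at AK089217, and lower at the locus of AB251227, DQ540368 and DQ552450, which share the same 3 peaks. Tmem171 rose by 1.16 (SE 0.11, adjusted p = 1.51e-05), 1700019C18Rik by 1.12 and AK089217 by 0.92, while AB251227 fell by 0.72. SI NK libraries were also high at these higher loci, so such values were not particular to LI. NK had 6.68 and 6.86 at Tmem171, 6.31 and 6.48 at 1700019C18Rik and 6.58 and 6.85 at AK089217. LI ILC1 replicates 4 and 3 had 6.49 and 6.45, 6.89 and 6.50, and 6.31 and 6.33 there. Other list genes were Ccr8 (0.91), Ccr9 (-0.56, adjusted p = 0.0039) and Ahrr, a repressor gene in aryl hydrocarbon signalling (-0.64, adjusted p = 0.00193). The 1503 higher peaks were 53.3% of calls, and 1318 fell. The share was 40.3% without LI ILC1 replicate 4 and 48.1% without SI ILC1 replicate 4. Without LI ILC1 replicate 3 the count was 455, on shared dates with the date as a block it was 912 and none of the named loci passed (adjusted p = 0.105). With thinned reads it was 612, and with voom 864, 89.0% of them higher.

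Within ILC3, LI cells had higher accessibility at Tmem171 (1.43, SE 0.11, adjusted p = 1.78e-06) and at Ctla2a and Tpbpa, which share 2 peaks (1.29). It was lower at Sorcs2, a sorting receptor gene (-0.87), AK206655 (-1.45) and Mir5126 (-1.31). At AK206655 the LI CCR6- ILC3 library was at the lowest value of 4.34. In lists, Cyp26b1, which degrades retinoic acid, fell by 0.72 (adjusted p = 0.00136), while Nmur1 (-0.42, adjusted p = 0.00641) and Prdm1 (-0.33) were also lower. There were 3709 higher and 7124 lower peaks, 34.2% higher, in 2 LI libraries that had a mean of 1610179 reads against 9204913 in SI. With voom 978 of 1076 calls were higher, 90.9%, and thinned reads gave 1010 higher and 1403 lower. In simulated libraries without any change this comparison called 566 peaks, 498 of them lower. Sex was partly mixed with tissue here. Each LI library had 1 Y-linked read and SI replicate 3 of both subsets had 0, while SI replicates 1 and 2 had 787 to 2034. With autosomal peaks only, 10656 peaks were called, 34.5% of them higher. That fit leaves out sex-linked peaks, and other effects of sex were not tested. On the only shared date limma called 0 peaks, with 8264 at an unadjusted p under 0.05, and the named loci had an adjusted p of 0.275.

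The tissue difference itself was tested between ILC1 and ILC3. LI minus SI in ILC1, less LI minus SI in ILC3, was positive at Dner, a Notch ligand gene (1.08, SE 0.14, adjusted p = 0.000253), and at Gm5901 and Olfr692, which share 1 peak (1.17), and negative at AB251227 (-0.87, SE 0.10, adjusted p = 9.89e-05). LI against SI gave 0.59 in ILC1 and -0.50 in ILC3 at Dner, 0.28 and -0.88 at Gm5901 and Olfr692, and -0.72 and 0.15 at AB251227, of which only Dner passed the threshold in both cell types. At Gm5901 and Olfr692 the only LI CCR6+ ILC3 library, the shallowest of all, was at the lowest value of 4.34, which stands for 0 reads. In the test of the difference itself 1351 peaks were higher and 472 lower, 74.1% higher. Thinned reads gave 15 calls and voom gave 12, 33.3% higher. Counts were 623 without LI ILC1 replicate 3, 1047 and 1115 without SI CCR6+ ILC3 replicates 1 and 2, and 1183 and 1070 without SI CCR6- ILC3 replicates 1 and 2.

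**Figure D3:**
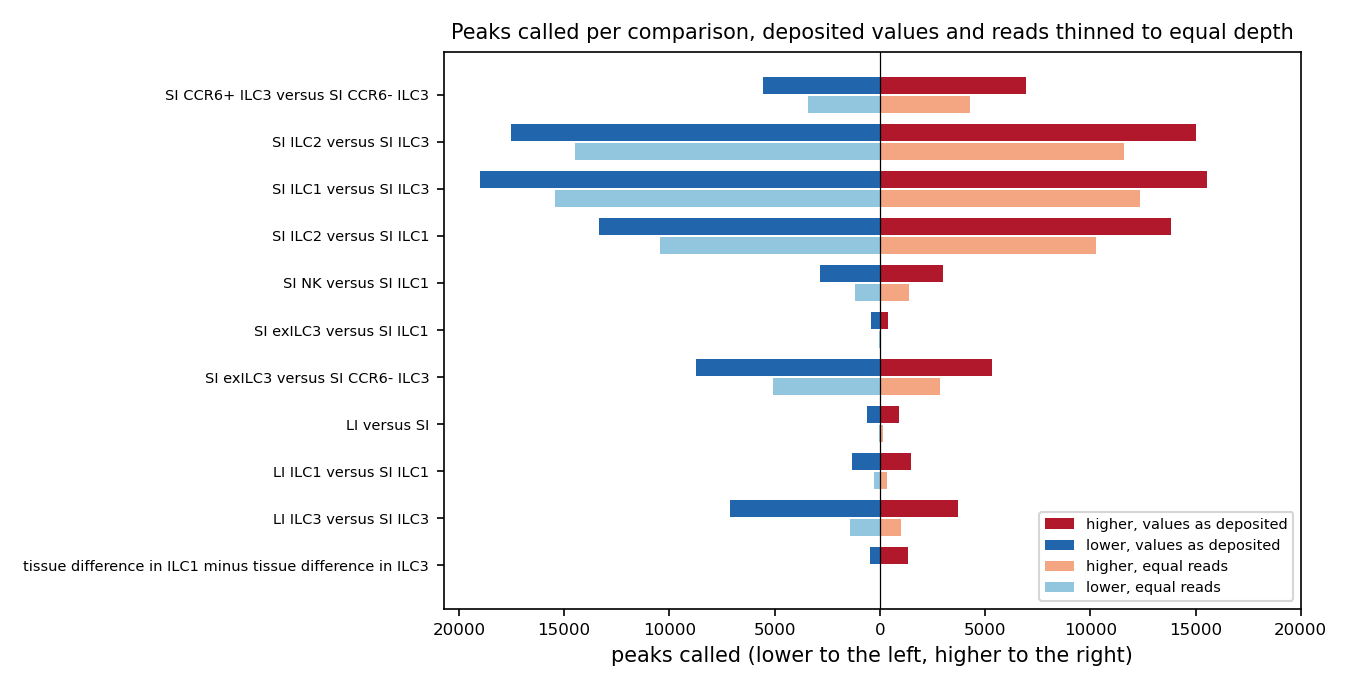
Number of peaks called lower (to the left) and higher (to the right) on x in each of the 11 comparisons on y, with dark bars for the values as deposited and pale bars for reads thinned to equal depth. ILC1 against ILC3 has 15547 higher and 18988 lower peaks, exILC3 against ILC1 398 and 411.

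Marker loci of other cell types were counted in the same comparisons. Of all 20345 loci, limma called 10090 in ILC2 against ILC3 and 10047 in ILC1 against ILC3. It called 3991 in CCR6+ against CCR6- ILC3 and 3712 in exILC3 against CCR6- ILC3. Differences between groups cannot show other cells that the groups share, so these counts do not measure the purity of the sorts. T cell loci (10 measured) had 3 higher and 2 lower in CCR6+ against CCR6- ILC3, with Cd28 at 0.74, and 6 and 2 in ILC1 against ILC3, with Trat1 at 2.11. They had 5 and 1 in ILC2 against ILC3, with Themis at 1.33, and 2 and 1 in exILC3 against CCR6- ILC3. B cell loci (6 measured) had 0 higher and 4 lower in ILC1 against ILC3, with Blk at -1.49 (adjusted p = 0.00597 for the list, and adjusted p = 0.302 with an estimated correlation), and 1 and 3 in ILC2 against ILC3, with Blk at -1.70. Of 9 myeloid loci 4 were higher and 2 lower in ILC2 against ILC3, with Cebpa at 1.17, and 2 and 2 in ILC1 against ILC3, with Itgax at 1.62. Of 3 mast cell loci 1 was higher and 1 lower in ILC2 against ILC3, with Cpa3 at -0.50. Of 8 epithelial loci 1 was higher and 3 lower there, with Krt8 at -2.45, and 1 and 3 in ILC1 against ILC3, with Cdx1 at -1.23. Housekeeping promoters (12 measured) had 4 higher and 1 lower in ILC2 against ILC3, 3 and 1 in ILC1 against ILC3, with Gapdh at -0.40, and 0 called by limma in exILC3 against ILC1, with 1 at an unadjusted p under 0.05.

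Regulators (38 measured) had 2 higher and 8 lower loci in CCR6+ against CCR6- ILC3, 13 and 8 in ILC2 against ILC3, 17 and 9 in ILC1 against ILC3, 10 and 8 in ILC2 against ILC1, 1 and 2 in NK against ILC1, 1 and 0 in exILC3 against ILC1 and 3 and 1 in exILC3 against CCR6- ILC3.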

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

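The tests on the direction of LI ILC3 calls and on Y-linked reads, and the splits that part all pairs of LI and SI, were chosen only after those results had been seen, while the counts over other splits of the libraries were set beforehand.

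In SI ILC1, the only group of 4 libraries, 128 named values were tested for 1 library far from the other 3, and 8 had a gap, as a part of the whole range, above Dixon's critical value. Chance gives about 1 in 20 such gaps. Replicate 1 stood apart at Il17a (gap 0.83 of the range; 5.57 against 4.90 to 5.01), Hs3st1 (0.97), Pparg (0.92), Ret (0.944), Sorcs2 (0.865) and the Pyroxd1 peak (0.914; 5.79 against 5.26 to 5.31). Replicate 4 stood apart at Ikzf2 (0.927) and at the Park2 peak (0.849; 5.64 against 6.14 to 6.23). The cause was not tested.

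The difference between tissues differed between ILC1 and ILC3 at 1823 peaks, by a test of that difference itself. LI minus SI in ILC1, less LI minus SI in ILC3, was positive at the loci of Dner (1.08) and of Gm5901 and Olfr692 (1.17), and negative at the locus shared by AB251227, DQ540368 and DQ552450 (-0.87). With thinned reads this test called 15 peaks. At Gm5901 and Olfr692 the LI CCR6+ ILC3 library was at the lowest value of 4.34.

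The authors' deposited table held comparisons of groups that are not among the 23 libraries. For SI CCR6- ILC3 it called 191 peaks between the conditions it names spfSFB and monoSFB, 148 higher and 43 lower, of 42426 with an adjusted p-value. Between monoSFB and GF the authors' deposited table called 1 of 6528 peaks. No library of these conditions was analysed here, so no explanation was tested.

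Lower peaks made up 65.8% of the calls between LI and SI ILC3, and the LI libraries were shallower, so lower depth could have made them. With every library thinned to the same reads, the number of calls was 22.3% of that reported, within the 10.3% to 80.5% in comparisons between SI groups, so for the number of calls depth and tissue cannot be told apart. Lower peaks were still 58.1% of those calls (95% interval 56.1 to 60.1, Clopper-Pearson over peaks). They were 66.6% of the calls at peaks below the median read count and 53.7% at peaks above it. An excess thus remained at equal reads and was larger at low-read peaks. The interval is over peaks and not libraries, so it cannot decide whether depth is the whole cause. With voom 978 of 1076 calls were higher, so a dependence on how low reads are transformed or weighted stays open. A tissue difference also stays open, since the only shared date had 1 library per subset and tissue.

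In LI ILC1 replicate 3, Y-linked peaks had 41.1 reads per 1000000 reads, between 14 libraries with 104.3 to 178.3 and 8 with 0 to 0.641, while its Xist reads (75.5 on that scale) lay within the 48.1 to 113.3 of the libraries without Y-linked signal. Reads of an ILC3 library mixed in, as the source of all its Y-linked reads, were argued against, because over peaks higher in ILC3 the library lay 99.5% of the way from ILC3 to ILC1, within the 80.01% to 110.7% of the other ILC1 libraries. Over peaks higher in ILC1 it lay 87.8% of that way, where the other ILC1 libraries lay at 94.7% to 104.5%, so ILC3 reads mixed in at a lower share stay open. Its Y-linked reads were 32.8% of the median of libraries that have them, which may come from animals of both sexes in the pool or from reads of an ILC1 library with Y-linked signal. These cannot be told apart, since either gives ILC1 chromatin with part of the Y-linked reads. SI ILC1 of the same date had 0.185 on that scale, and whether both tissues came from the same animals is not known. The sort of ILC1 and NK (107.6 and 124.9), NK replicate 1 (143.9) and LI exILC3 (104.3) had Y-linked signal too and were not tested as sources. No biological explanation was tested.

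For CCR6+ against CCR6- ILC3 the 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 12497 peaks and the highest other 0. For ILC1 against ILC3, 1 of 100 splits, the real one with 34535 peaks, gave so large a count, and chance can be excluded only for single libraries that vary independently. The highest other, 16643, set 3 ILC1 libraries with CCR6- ILC3 replicate 1 against the rest. No batch held both groups, and whole batches, 3 against 2, make 10 splits, too few for a share under 0.05. For LI against SI the real split with 1499 peaks was again the only 1 of 100 with so large a count, and the highest other gave 449, but most of these splits do not part the pairs. The 16 splits that part all 5 pairs, in which the others exchange LI and SI within pairs, are too few for a share under 0.05, and the highest other of them gave 0.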

How the results depend on the processing

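Among these alternatives, voom, thinned reads, autosomal peaks only and leaving out libraries in the 3 tissue comparisons of ILC1 and ILC3 were chosen after seeing the data.

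No named gene or peak changed direction, but the rule chose them for large differences or statistics in these same libraries. Kept directions and calls are thus weak evidence. Over all alternatives 2884 values of named genes and peaks kept their side of the threshold, 166 lost their call and 31 gained one, while 123 counts of calls were within 1.5 times the reported count and 57 were not. Autosomal peaks only kept all 11 counts within 1.5 times. Leaving out the peaks with the lowest mean values, quantile normalization and the spread without trend did so for the 8 comparisons of cell types or tissue and were not run for the 3 tissue comparisons of ILC1 and ILC3. No scaling moved the median of all peaks by over 0.1.

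A difference of at least 1 left, by construction, fewer peaks: 2660 for CCR6+ against CCR6- ILC3, 12670 for ILC2 against ILC3, 9357 for ILC1 against ILC3, 10385 for ILC2 against ILC1, 1349 for NK against ILC1, 126 for exILC3 against ILC1, 3763 for exILC3 against CCR6- ILC3 and 117 for LI against SI. With batch as a term the counts were 18602 for ILC1 against ILC3, 13797 for ILC2 against ILC1, 10863 for NK against ILC1 and 2121 for exILC3 against ILC1. For ILC1 against ILC3 and ILC2 against ILC1, these fits rest on the difference between SI exILC3 replicates 3 and 4, which alone link the batches. Only the compared libraries in the fit gave 2379 for NK against ILC1 and, by limma, 0 for exILC3 against ILC1, with 6159 at an unadjusted p under 0.05. All 23 libraries in the fit gave 12262 for LI against SI. Voom gave 19030 for CCR6+ against CCR6- ILC3, 2537 for NK against ILC1, 1923 for exILC3 against ILC1, 864 for LI against SI ILC1, 1076 for LI against SI ILC3 and 12 for the difference between these. Thinned reads gave, in that order, 7656, 2555, 83, 612, 2413 and 15, and 7919 for exILC3 against CCR6- ILC3 and 158 for LI against SI. Taking the largest peak of a locus called 714 loci for NK against ILC1 and 502 for LI against SI. The cause of the other changes was not tested, except that thinned reads hold less depth by construction.

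Within batches, SILP alone gave 1023 peaks for NK against ILC1, and the shared date of LI and SI ILC3 gave 0 by limma, with 8264 at an unadjusted p under 0.05 and 1076 by voom over all libraries. With the replicate number as a block, 12686 peaks were called for CCR6+ against CCR6- ILC3, 2362 for NK against ILC1, whose same-numbered libraries shared little (correlation across peaks 0.0346), and 3644 for exILC3 against ILC1. With the 5 pairs of LI and SI as a replicate block 1399 were called, and 912 for LI against SI ILC1 on shared dates.

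Leaving out 1 library at a time gave 7894 to 12015 peaks for CCR6+ against CCR6- ILC3 (fewest without CCR6- ILC3 replicate 1), 23614 to 31786 for ILC2 against ILC3, 31612 to 34529 for ILC1 against ILC3 and 18745 to 27148 for ILC2 against ILC1. It gave 1355 to 7690 for NK against ILC1 (fewest without NK replicate 2), 137 to 2256 for exILC3 against ILC1 (without SI ILC1 replicates 3 and 1) and 7615 to 12166 for exILC3 against CCR6- ILC3 (fewest without SI exILC3 replicate 3). For LI against SI the range was 436 to 1614 (fewest without LI exILC3), for ILC1 across tissues 455 to 3272 (fewest without LI ILC1 replicate 3), for ILC3 across tissues 8657 to 10982, and for the difference between these 623 to 2497 (fewest without LI ILC1 replicate 3). In these last 2 comparisons neither LI ILC3 library was left out, since each is the only one of its group, so the dependence on them was not tested. Where a group was left with 1 library, it was assumed to vary like the other groups.

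With equal reads the number of calls was 10.3% of that reported for exILC3 against ILC1, 10.5% for LI against SI and 0.82% for the difference between tissues in ILC1 and ILC3, against 80.5% for ILC1 against ILC3.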

Other observations

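The deposited motif hits split called peaks by cell type. Of peaks higher in CCR6+ than in CCR6- ILC3, 31.8% held an NF-kB hit against 11.8% of lower peaks (odds ratio 3.49), while T-box hits were in 13.6% and 32.2% (odds ratio 0.332). GATA hits were in 18.6% of peaks higher in ILC2 than in ILC3 and in 12.3% of lower peaks. Between ILC1 and ILC3, T-box hits were in 26.7% of higher and 13.7% of lower peaks. GATA hits were in 19.6% of peaks higher in ILC2 than in ILC1 and in 10.97% of lower peaks. Peaks higher in NK than in ILC1 held GATA hits in 11.2% of cases against 18.9% of lower peaks (odds ratio 0.542, adjusted p = 5.32e-16, Fisher's exact test over peaks). In exILC3 against ILC1, T-box hits were in 21.1% of the higher and 34.1% of the lower peaks (odds ratio 0.518). In exILC3 against CCR6- ILC3, T-box hits were in 34.2% and 14.9%. In LI against SI, GATA hits were in 12.4% of higher and 18.8% of lower peaks (odds ratio 0.613), and AP-1 hits in 55.98% and 47.4%. Peaks are not independent replicates, and these tests take no account of the spread between libraries.

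The sort of ILC1 and NK lay closer to ILC1 than to NK. Over peaks higher in NK its libraries lay 20.8% and 15.96% of the way from ILC1 to NK, and over lower peaks 15.9% and 10.8%. LI ILC1 lay 31.3% and 37.3% of that way over higher peaks and 32.5% and 33.1% over lower peaks. Over peaks higher in ILC1 the exILC3 libraries lay 73.6% to 77.5% of the way from ILC3 to ILC1, and SI ILC1 libraries 94.7% to 104.5%. Over peaks higher in ILC3 the exILC3 libraries lay 69.9% to 82.8% of that way, which included SI ILC1 replicate 1 at 80.01%, while the other SI ILC1 libraries lay at 98.99% to 110.7%. LI exILC3 lay 67.6% of the way from SI to LI ILC1 over higher peaks and 50.7% over lower peaks, and SI exILC3 lay at -12.4% and -6.72%, and at 5.78% and -0.761%. SI NK lay 55.3% and 67.9% of that way over higher peaks and 30.04% and 47.2% over lower peaks, so such a position was not particular to LI.

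The authors' deposited table called 11883 peaks between SI CCR6+ and CCR6- ILC3, 5967 higher, and 10880 of them were also called with limma, all in the same direction, where independent lists would share 2274.8. For ILC2 and ILC1 the authors' deposited table called 26267, of which 25268 were shared, against 10946.3 by independent lists. For NK and ILC1 the authors' deposited table called 2869, of which 2811 were shared, and for LI and SI ILC1 1418, of which 1345 were shared. It covers the same cell groups, peaks and series, so the overlap is no independent evidence. Between LI and SI the authors' deposited table called 1306 peaks in CCR6- ILC3, 750 higher, and 585 in CCR6+ ILC3, 335 higher, so lower peaks were the smaller part in both. In LI it called 14 peaks between CCR6+ and CCR6- ILC3, of 32634 with an adjusted p-value. The LI libraries of these subsets had no replicates here and were the shallowest of all, with 1559604 and 1660754 reads in peaks. That count thus cannot show how far the subsets differ in LI, nor be set against the count in SI.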
